A study of Arabidopsis thaliana with 9 samples.

How the data were processed

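Roots of 3 groups of Col-0 plants, each with 3 libraries, were measured by RNA-seq. Per the labels' protocols, RNA was extracted with Trizol and the libraries were strand-specific. Groups were taken from the labels. The submitters' processing notes name Bowtie2 2.3.4.1, STAR 2.5.0c, Cufflinks 2.2.1 and the TAIR10 genome, and the role of each tool is not given in the sources used here. For each library the authors deposited FPKM per gene, which are fragments scaled to transcript length and to the number of mapped fragments, with a status column. How these FPKM were scaled between libraries is not given in the sources used here. The authors' deposited table of both stresses against control holds log2 fold changes, and the p-values and q-values of the authors' test, whose name is not given in the sources used here. Each file of a library held 37547 genes. 5 genes with 6 values of a status other than OK were dropped.

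Values were tested on the log2(FPKM + 1) scale for the 19536 genes with a mean of at least 1 FPKM over the 9 libraries. limma 3.58.1 with an intensity trend (R 4.3.3) was fitted as a one-way model of the 9 libraries, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. The comparisons were cesium against control, low potassium against control, and cesium against low potassium. FPKM are not counts, so no count model was used. Gene lists were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01, adjusted over 28 lists. They were tested again with a correlation estimated for each list, and with fry. Of 475 list entries 473 matched a gene of the files, and 418 were tested. Lists of 12 clock genes and of 12 shoot genes outside photosynthesis were added after the files were seen. Gene names came from a RefSeq table of TAIR10.1, in which 37045 of the identifiers matched, and coordinates are those of the files on TAIR10, counted from 1. For part of the genes the files give a region that spans neighbours, 27467 of the 37045 compared having the region of the reference gene alone.

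The genes named for each comparison were the 6 with the highest and the 6 with the lowest log2 change among those that passed, had no overlap between the libraries of both groups and reached a mean of 5 FPKM in the higher group. To these were added tested thiamine genes, HAK5 and AKT1, and the 3 genes with the smallest adjusted p in each of the lists of ABA receptors, phosphatases and kinases, ABA-responsive genes and potassium transport and of up to 4 further lists with the smallest camera p. From any other list described, up to 2 genes with the smallest adjusted p were named.

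Relative depth was read from FPKM under 0.5, a check chosen after the files were seen. Ratios of the same gene between 2 libraries pile up at the ratio of what 1 read is worth, and 12.7% to 18.4% of the compared genes lay within 0.015 of it on the log2 scale. This ratio stands for mapped reads or for the authors' scaling factor. The steps were tested on simulated data. The limma and camera steps were also tested on simulated values of the 19536 genes for cesium against control, with 200 genes changed. Of those changed by 1 on the log2 scale, 93.0% were recovered, and of those changed by 2, 100%. Of the unchanged genes 14 were called.

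Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median-ratio and quantile scaling, a fit on 6 libraries, a replicate block, limma without the trend, a log2 change of at least 1, the authors' q-values and leaving out each library. Leaving out genes listed at 0 in 1 library was added after the data were seen. Unchanged groups that share their controls were simulated 50 times, with the controls drawn as well. Random lists matched on mean expression numbered 10000. Scripts ran in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.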

Results

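RNA of Arabidopsis thaliana Col-0 roots was measured in 9 libraries, 3 for each of 3 growth conditions. Control roots were given 0.5 mM KCl and low-potassium roots 0.025 mM KCl. Cesium roots were given 0.5 mM KCl together with CsCl, whose amount the labels write as 0.3 with mL as the unit. Cesium is an alkali metal that resembles potassium and can enter roots through potassium transporters. The labels call the libraries biological replicates without saying that they came from separate cultures, so p-values then measure only the spread between these samples, which may be technical. The values are FPKM, and read totals are not given. The steps between low FPKM values, which show what 1 read is worth, put the depth of the libraries between 97.3% and 102% of that of control replicate 1, as far as the authors' scaling allows this to be read. Absolute depth remained unknown, so no counting error could be set beside single values. FPKM summed to 715298 to 845355 per library, and 19172 to 19481 genes reached 1 FPKM.

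The first principal component (39.3% of the variance) set the low-potassium libraries apart from the others, and the next (31.0%) set cesium apart from control. Cesium replicate 3 stood apart from the other cesium libraries on the next component (12.2%), where it scored 0.71 against -0.52 and -0.37. In that library MT1A, a metallothionein gene, was listed at 0, against 65213 to 94117 FPKM in the others. The highest correlation of any pair of libraries across genes was 0.989. Below, FPKM are given as mean ± SD (n = 3) and changes as log2 change ± SE on the log2(FPKM + 1) scale, which understates changes of low genes. Genes were named by a rule fixed, like the gene lists, before the data were examined. List members named because a count was 5 or fewer, and those of the lists as a whole where all are named, were chosen after their values were seen. On TAIR10, in the regions given by the files, THIC (AT2G29630) lies on chromosome 2, 12666832 to 12671055, THI1 (AT5G54770) on chromosome 5, 22246519 to 22248332, HAK5 (AT4G13420) on chromosome 4, 7796782 to 7802251, AKT1 (AT2G26650) on chromosome 2, 11329719 to 11336738, PYL6 (AT2G40330) on chromosome 2, 16844588 to 16846194 and RAB18 (AT5G66400) on chromosome 5, 26518277 to 26525177. The files give a region shared with other genes for AIR1, LHCB1.3, JAZ10, HSP17.4, PSAG, THIC, NRAMP1, PDX1.1, PYL7, TPK2, TH1, TENA_E, AKT1, FER1, ABI1, BHLH101, ABF3, NPF7.3, PER64, TIP2.1, PAP17, LEA7, AT1G52820, RAB18, FAR1, KNOLLE, FER4, WRKY33, FAR4 and CASP5, so their values are less certain, as are those of genes with near-identical copies such as RBCS1A, LHCB1.3, KIN1 and NRT2.2.

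Cesium was set against control to find which root transcripts respond to cesium at the control potassium supply, with the series title naming ABA perception and thiamine synthesis. In cesium roots THIC, which makes the pyrimidine part of thiamine, rose from 6.25 ± 1.92 to 12.9 ± 3.15 FPKM (log2 change 0.94 ± 0.20, adjusted p = 0.00832). AIR1, found as an auxin-induced gene of root cultures, rose from 232 ± 36.9 to 5279 ± 1769 FPKM (log2 change 4.47 ± 0.21, adjusted p = 6.12e-06), and CYP710A4, a cytochrome P450 of sterol synthesis, rose from 1.41 ± 0.213 to 133 ± 67.5 FPKM (log2 change 5.67 ± 0.31, adjusted p = 6.82e-06). SPX1, a sensor of phosphate status, fell from 36.3 ± 5.54 to 6.83 ± 0.339 FPKM (log2 change -2.24 ± 0.11, adjusted p = 6.12e-06), and RD29A, a marker of ABA and cold responses, fell from 58.3 ± 13.6 to 11.2 ± 1.84 FPKM (log2 change -2.26 ± 0.26, adjusted p = 0.000375). Of 19536 genes tested with limma, 4591 passed an adjusted p of 0.05, 2116 higher and 2475 lower in cesium, and 934 of them changed by at least 1 on the log2 scale.

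Of the 7 thiamine biosynthesis genes, 1 rose, THIC (1 adjusted over the list alone). The title names these genes, so the list is not independent evidence of its direction. THI1, the thiazole-forming enzyme and the most abundant of them, measured 46.8 ± 10.3 FPKM in control and 71.5 ± 21.2 in cesium and did not pass (log2 change 0.58 ± 0.23, adjusted p = 0.103). THI1 passed without cesium replicate 3 (adjusted p = 0.0129), with a log2 change of 0.83. THI1 had adjusted p from 0.0129 to 0.277 over 19 alternatives. Members that did not pass either include TPK2 (0.37 ± 0.16), TH1 (0.17 ± 0.077), TENA_E (0.087 ± 0.14) and TH2 (-0.031 ± 0.14), the last turning its sign without each of 4 single libraries. The list as a whole had a median log2 change of 0.17. Thiamine genes as a set had a camera adjusted p of 0.0997, and an adjusted p of 0.441 with an estimated correlation. Of the 4 vitamin B6 genes, PDX1.1 (0.62 ± 0.18) and PDX2 (0.30 ± 0.087) rose (adjusted over the list alone, 2 rose and 1 fell). PDX1.1 lost its call with no filter on low values (adjusted p = 0.0556), in a fit on 6 libraries (0.0595), without control replicate 1 (0.0835), cesium replicate 1 (0.0940) or cesium replicate 2 (0.0800). PDX1.1 had adjusted p from 0.0170 to 0.0940 over 19 alternatives. PDX2 lost it in a fit on 6 libraries (adjusted p = 0.0523), without control replicate 1 (0.0590), control replicate 2 (0.0922), control replicate 3 (0.0989), cesium replicate 1 (0.0989) or cesium replicate 3 (0.0559). PDX2 had adjusted p from 0.0230 to 0.0989 over 19 alternatives. In low potassium 1 of the 4 vitamin B6 genes rose and 1 fell, and between cesium and low potassium 0 passed. In the authors' deposited table THIC changed by 1.04 and THI1 by 0.61 in log2, each with a q of 0.000491. That q is the lowest among the named genes and shared by many, so it does not rank THI1 with THIC.

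Among 10 tested genes of ABA receptors, which the title also names, 5 fell and 1 rose (adjusted over the list alone, 1 rose and 5 fell). Those that fell were PYL3 (-1.29 ± 0.24), PYL6 (-0.58 ± 0.13), PYL9 (-0.36 ± 0.093), PYL1 (-0.36 ± 0.10) and PYL2 (-0.41 ± 0.13), and PYL7 (0.52 ± 0.12) rose. The call of PYL6 ended without control replicate 2 (adjusted p = 0.0530) or control replicate 3 (0.0518), and that of PYL7 without control replicate 2 (adjusted p = 0.0528). PYL6 had adjusted p from 0.00809 to 0.0530 over 19 alternatives. PYL7 had adjusted p from 0.00511 to 0.0528 over 19 alternatives. The receptor list as a set did not pass (median -0.23). ABA receptor genes as a set had a camera adjusted p of 0.166, and an adjusted p of 0.535 with an estimated correlation. Of 11 phosphatases and kinases that act just after the receptors, 4 fell (4 adjusted over the list alone): the kinase OST1 (-0.58 ± 0.10), the phosphatases ABI1 (-0.44 ± 0.092) and HAI3 (-1.1 ± 0.29), and SNRK2.3 (-0.38 ± 0.12). The phosphatases among them are known to hold ABA signalling down and the kinases to carry it forward. That list passed, though not without control replicate 2 (adjusted p = 0.101). Phosphatase and kinase genes as a set had a camera adjusted p of 0.0237, and an adjusted p of 0.535 with an estimated correlation. Phosphatase and kinase genes as a set had camera adjusted p from 0.00297 to 0.101 over 17 alternatives. HAI3 lost its call without control replicate 2 (adjusted p = 0.0995), control replicate 3 (0.0519), cesium replicate 1 (0.0680), cesium replicate 2 (0.0519) or cesium replicate 3 (0.0558). HAI3 had adjusted p from 0.00537 to 0.0995 over 18 alternatives. PYL9 lost its call without control 1, control 3, cesium 1 or cesium 2 (adjusted p from 0.00701 to 0.0762 with single libraries left out), PYL1 without control 3, cesium 1 or cesium 2 (0.0333 to 0.108), PYL2 without each of 8 libraries in turn (0.0469 to 0.118) and SNRK2.3 without each of 7 libraries in turn (0.00845 to 0.104).

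Among 18 genes known to respond to ABA, 8 fell (adjusted over the list alone, 2 rose and 11 fell), with log2 changes of -2.26 to -0.79, and the set passed. ABA-responsive genes as a set had a camera adjusted p of 0.000266, and an adjusted p of 0.487 with an estimated correlation. COR47 fell from 544 ± 55.1 to 174 ± 8.58 FPKM (log2 change -1.64 ± 0.16, adjusted p = 0.000159), and ABF3, a transcription factor of the ABA response, fell from 102 ± 6.63 to 58.6 ± 3.29 FPKM (log2 change -0.79 ± 0.10, adjusted p = 0.000491). Of 9 genes of ABA synthesis and breakdown, CYP707A4, which breaks ABA down, and BG1, which frees ABA from its glucose ester, rose (3.18 ± 0.24 and 2.14 ± 0.29), and CYP707A3 (-0.32 ± 0.10) fell (adjusted over the list alone, 2 rose and 1 fell). The median of that list was -0.075, its mean 0.54 and the direction of its test upward. ABA synthesis and breakdown genes as a set had a camera adjusted p of 0.497, and an adjusted p of 0.673 with an estimated correlation. CYP707A4 went from 0.124 ± 0.0709 to 9.69 ± 4.39 FPKM. HAK5, the high-affinity potassium transporter, measured 4.2 ± 0.465 FPKM in control and 3.32 ± 1.38 in cesium (log2 change -0.31 ± 0.19, adjusted p = 0.253) and passed without cesium replicate 2 (adjusted p = 0.0120), there with a log2 change of -0.56. HAK5 had adjusted p from 0.0120 to 0.624 over 19 alternatives. The channel AKT1 measured 56.1 ± 2.02 and 56.1 ± 9.62 FPKM (log2 change -0.014 ± 0.11, adjusted p = 0.942). Its sign turned under quantile normalization (log2 change 0.020, adjusted p = 0.914), without control replicate 2 (log2 change 0.0053, adjusted p = 0.985) and without cesium replicate 3 (log2 change 0.13, adjusted p = 0.177). Of 34 potassium transport genes, 2 rose and 4 fell (adjusted over the list alone, 2 rose and 4 fell), among them KUP6 (0.39 ± 0.084) and HKT1 (0.54 ± 0.16) upward and GORK (-0.67 ± 0.10), NPF7.3 (-0.80 ± 0.13), KUP1 (-0.44 ± 0.12) and CBL9 (-0.30 ± 0.085) downward. Potassium transport genes as a set had a camera adjusted p of 0.255, and an adjusted p of 0.717 with an estimated correlation. CYP707A3 lost its call without each of 8 libraries in turn (adjusted p from 0.0206 to 0.150 with single libraries left out), HKT1 without each of 6 libraries in turn (0.0216 to 0.105), KUP1 without control 2, control 3, cesium 1 or cesium 2 (0.00821 to 0.0973) and CBL9 without each of 5 libraries in turn (0.0183 to 0.0887).

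Of 20 jasmonate genes, 15 rose (16 adjusted over the list alone), with log2 changes of 0.45 to 1.69. Jasmonate genes as a set had a camera adjusted p of 6.04e-08, and an adjusted p of 0.345 with an estimated correlation. Those with the smallest p were JAZ6, JAZ10 and JAZ1, which encode repressors that jasmonate itself induces, and JAZ1 rose from 87.1 ± 8.81 to 204 ± 24.2 FPKM (log2 change 1.22 ± 0.12, adjusted p = 0.000162). Of 29 nuclear photosynthesis genes that passed the expression filter in these roots, of 33 listed, 24 rose (26 adjusted over the list alone), with a median of 1.0. Photosynthesis genes as a set had a camera adjusted p of 3.84e-11, and an adjusted p of 0.487 with an estimated correlation. LHCB1.3, a chlorophyll-binding protein gene, rose from 156 ± 18.1 to 574 ± 152 FPKM (log2 change 1.85 ± 0.18, adjusted p = 0.000143), and RBCS1A, a Rubisco subunit gene, rose from 89.6 ± 24.6 to 385 ± 105 FPKM (log2 change 2.09 ± 0.23, adjusted p = 0.000273). Chloroplast-encoded genes took 0.184 to 0.468% of summed FPKM in the cesium libraries, with cesium replicate 3 highest, against 0.0802 to 0.125% in control. Of 12 shoot genes outside photosynthesis, 1 reached a mean of 1 FPKM, ATML1, at 1.92 in control and 2.71 in cesium. Of 15 heat shock genes 7 rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell), with HSP17.4 (1.60 ± 0.17) and HSP17.6A (1.71 ± 0.29) as examples and HSP26.5 (-0.69 ± 0.21) as the member that fell. Heat shock genes as a set had a camera adjusted p of 0.0264, and an adjusted p of 0.581 with an estimated correlation. The set no longer passed without control replicate 3 (adjusted p = 0.0537), cesium replicate 1 (0.0889) or cesium replicate 2 (0.0792). Heat shock genes as a set had camera adjusted p from 0.00278 to 0.0889 over 17 alternatives. HSP26.5 lost its call without each of 5 libraries in turn (adjusted p from 0.0230 to 0.140 with single libraries left out).

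Of 20 root hair genes, 13 fell in cesium (20 adjusted over the list alone), with RSL2 (-1.77 ± 0.31) and COW1 (-1.51 ± 0.28). Root hair genes as a set had a camera adjusted p of 6.04e-08, and an adjusted p of 0.535 with an estimated correlation. Of 9 genes of the Casparian strip, the barrier in the wall of the endodermis, 7 fell (7 adjusted over the list alone), and CASP2, which builds the membrane scaffold of the strip, fell from 126 ± 8.79 to 50.2 ± 8.17 FPKM (log2 change -1.32 ± 0.11, adjusted p = 8.16e-05). Casparian strip genes as a set had a camera adjusted p of 8.04e-07, and an adjusted p of 0.345 with an estimated correlation. Of 11 suberin genes, 10 fell (10 adjusted over the list alone), with the acyltransferase GPAT5 falling from 29.1 ± 3.27 to 10.2 ± 0.664 FPKM (log2 change -1.42 ± 0.11, adjusted p = 4.66e-05) and the transporter ABCG6 by a log2 change of -1.70 ± 0.14. Suberin genes as a set had a camera adjusted p of 1.38e-09, and an adjusted p of 0.345 with an estimated correlation. The 13 xylem wall genes had a median of -0.28. Xylem genes as a set had a camera adjusted p of 0.220, and an adjusted p of 0.774 with an estimated correlation. The xylem list passed without cesium replicate 2 (adjusted p = 0.0227), there with a median of -0.60. Xylem genes as a set had camera adjusted p from 0.0227 to 0.953 over 17 alternatives. Of 18 dividing cell genes, PLT2 (0.58 ± 0.13) and WOX5 (0.76 ± 0.18), regulators of the root stem cell niche, rose (2 adjusted over the list alone), and the set did not pass. Dividing cell genes as a set had a camera adjusted p of 0.434, and an adjusted p of 0.814 with an estimated correlation. WOX5 lost its call without control replicate 3 (adjusted p = 0.0506). WOX5 had adjusted p from 0.00570 to 0.0506 over 18 alternatives. Of the 5 phloem genes, APL (0.57 ± 0.10) and SUC2 (0.97 ± 0.22) rose (2 adjusted over the list alone). Phloem genes as a set had a camera adjusted p of 0.242, and an adjusted p of 0.673 with an estimated correlation.

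Of 13 phosphate starvation genes, 12 fell in cesium (12 adjusted over the list alone), with log2 changes of -2.92 to -0.39. Phosphate genes as a set had a camera adjusted p of 7.62e-10, and an adjusted p of 0.102 with an estimated correlation. IPS1, a noncoding RNA induced when phosphate is short, fell from 8.82 ± 0.796 to 0.325 ± 0.351 FPKM (log2 change -2.92 ± 0.18, adjusted p = 1.45e-05), and the phosphatase gene PAP17 by a log2 change of -1.79 ± 0.16. Of 24 nitrogen genes, 10 fell and 2 rose (adjusted over the list alone, 3 rose and 13 fell), with the glutamine synthetase gene GLN1.1 falling from 735 ± 50.2 to 365 ± 39.2 FPKM (log2 change -1.01 ± 0.13, adjusted p = 0.000706) and LBD39 (0.47 ± 0.12) and NRT1.8 (0.99 ± 0.27) rising. Nitrogen genes as a set had a camera adjusted p of 0.00132, and an adjusted p of 0.552 with an estimated correlation. Of 17 aquaporins, 10 fell and 2 rose (adjusted over the list alone, 2 rose and 12 fell), and TIP2.1, a water channel of the vacuole, fell from 488 ± 10.7 to 172 ± 40.5 FPKM (log2 change -1.53 ± 0.15, adjusted p = 0.000143), while PIP2.5 (1.28 ± 0.23) and PIP2.8 (0.40 ± 0.093) rose. Aquaporin genes as a set had a camera adjusted p of 3.24e-05, and an adjusted p of 0.441 with an estimated correlation. Of 24 iron deficiency genes, 6 fell and 2 rose (adjusted over the list alone, 2 rose and 6 fell), among them BHLH101 (-0.78 ± 0.13) downward and NRAMP1 (0.68 ± 0.10) and MYB10 (0.50 ± 0.15) upward. Iron genes as a set had a camera adjusted p of 0.0173, and an adjusted p of 0.552 with an estimated correlation. The iron list did not pass with a filter of 5 FPKM (adjusted p = 0.0722), without control replicate 3 (0.0653) or cesium replicate 3 (0.230). Iron genes as a set had camera adjusted p from 0.00270 to 0.230 over 17 alternatives. Of 13 sulfur deficiency genes, SDI1 (-1.76 ± 0.22), SULTR1.1 (-1.19 ± 0.22), SDI2 (-0.57 ± 0.12) and SHM7 (-0.37 ± 0.10) fell (5 adjusted over the list alone). Sulfur genes as a set had a camera adjusted p of 0.0102, and an adjusted p of 0.535 with an estimated correlation. The sulfur set did not pass without control replicate 3 (adjusted p = 0.0537) or cesium replicate 3 (0.0685). Sulfur genes as a set had camera adjusted p from 0.00226 to 0.0685 over 17 alternatives. LBD39 lost its call without control 1 or control 2 (adjusted p from 0.00406 to 0.0784 with single libraries left out), NRT1.8 without control 1, control 2, cesium 1 or cesium 2 (0.000919 to 0.0928), PIP2.8 without control 3 (0.0122 to 0.0548), MYB10 without each of 6 libraries in turn (0.0235 to 0.141) and SHM7 without control 2, control 3, cesium 2 or cesium 3 (0.0224 to 0.0820).

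Beyond the lists, the genes that rose most in cesium by the rule included LCR85, a cysteine-rich peptide gene, at 47.6, 34.3 and 111 FPKM in the cesium libraries, 0.816, 0.542 and 0.606 in control and listed at 0 in each low-potassium library. The gene AT4G22610, of a lipid-transfer protein family, rose from 5.38 ± 1.76 to 105 ± 19.7 FPKM (log2 change 4.08 ± 0.19, adjusted p = 6.12e-06). Those that fell most included AT1G52820, of a family of iron-dependent oxygenases (log2 change -4.28 ± 0.23, adjusted p = 6.59e-06), FTM1, of the stearoyl-ACP desaturase family (log2 change -3.35 ± 0.17, adjusted p = 6.12e-06), and LEA7, a late embryogenesis abundant gene (log2 change -3.50 ± 0.57, adjusted p = 0.00241). For 41.1% of tested genes the cesium and control libraries did not overlap, where chance gives 10.0%. Without control replicate 2 the count of changed genes was 2905, and without control replicate 3 it was 3030.

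**Figure D1:**
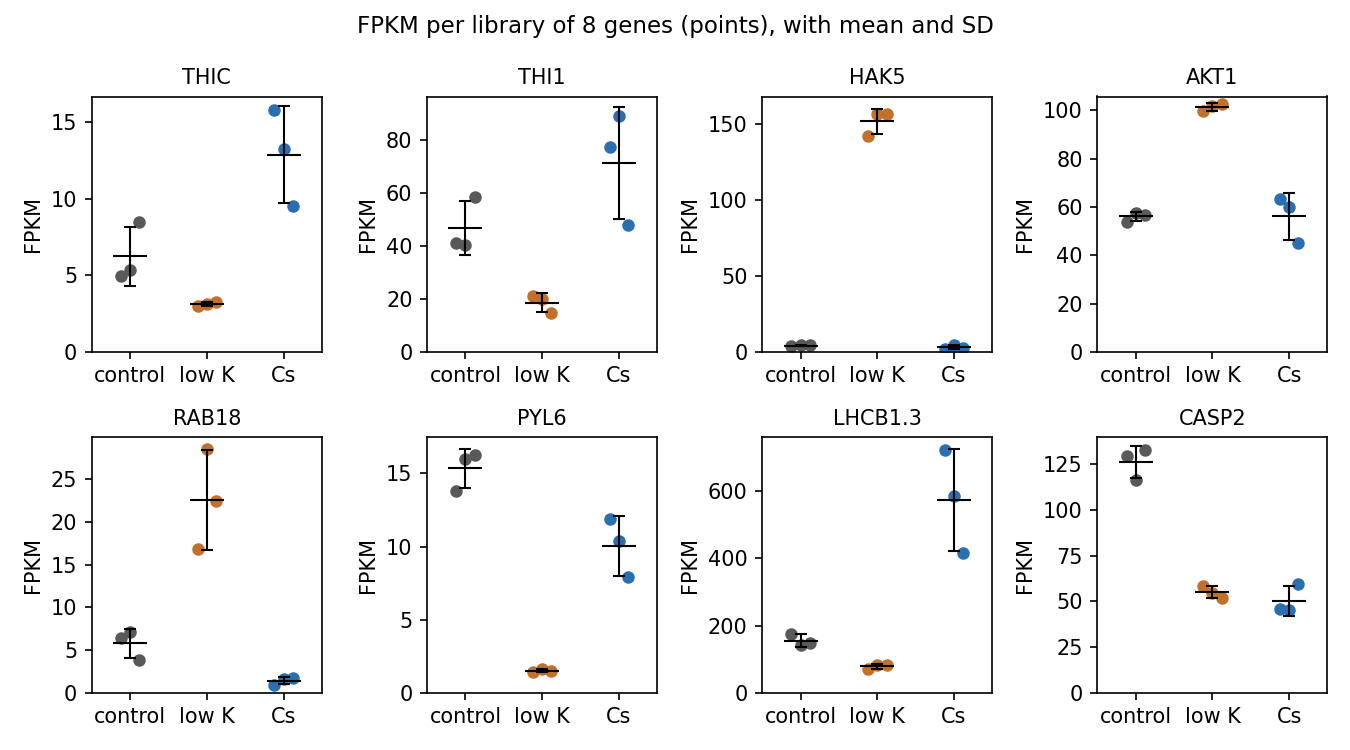
FPKM of THIC, THI1, HAK5, AKT1, RAB18, PYL6, LHCB1.3 and CASP2 in each of the 9 libraries by group, with the mean and SD of the 3 libraries of each group. HAK5 reached 152 ± 8.45 FPKM in low potassium against 4.2 ± 0.465 in control, while THIC was highest in cesium at 12.9 ± 3.15 FPKM.

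Low potassium was set against control to find the root response to potassium shortage. HAK5 rose from 4.2 ± 0.465 to 152 ± 8.45 FPKM (log2 change 4.88 ± 0.19, adjusted p = 1.99e-06), and AKT1, the main inward potassium channel of roots, rose from 56.1 ± 2.02 to 101 ± 1.53 FPKM (log2 change 0.84 ± 0.11, adjusted p = 0.000585). The dehydrin gene RAB18 rose from 5.81 ± 1.71 to 22.6 ± 5.84 FPKM (log2 change 1.8 ± 0.23, adjusted p = 0.000457), while PYL6, an ABA receptor gene, fell from 15.3 ± 1.35 to 1.53 ± 0.120 FPKM (log2 change -2.69 ± 0.13, adjusted p = 3.19e-06). RAB18 did not pass in the authors' deposited table (q of 0.0679 in low potassium). NRT2.4, a high-affinity nitrate transporter gene, fell from 17.9 ± 3.15 to 0.398 ± 0.197 FPKM (log2 change -3.75 ± 0.16, adjusted p = 1.99e-06), and MYB28, the regulator of aliphatic glucosinolate synthesis, fell from 56.5 ± 3.52 to 20 ± 3.48 FPKM (log2 change -1.47 ± 0.12, adjusted p = 3.95e-05). Of the 19536 tested genes 7340 passed with limma, 3669 higher and 3671 lower, and 1196 of them by at least 1 on the log2 scale.

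Of 34 potassium transport genes, 14 rose and 6 fell (adjusted over the list alone, 14 rose and 6 fell). Potassium transport genes as a set had a camera adjusted p of 0.00984, and an adjusted p of 0.631 with an estimated correlation. CIPK9, a kinase of the response to potassium shortage, rose from 2.09 ± 0.605 to 15.2 ± 1.0 FPKM (log2 change 2.41 ± 0.16, adjusted p = 1.22e-05), and the permease gene KUP10 rose from 10.9 ± 0.936 to 34.2 ± 1.82 FPKM (log2 change 1.57 ± 0.090, adjusted p = 5.15e-06). The thiamine list went both ways, with THI1 falling from 46.8 ± 10.3 to 18.7 ± 3.42 FPKM (log2 change -1.28 ± 0.23, adjusted p = 0.00268) and THIC falling from 6.25 ± 1.92 to 3.13 ± 0.120 FPKM (log2 change -0.78 ± 0.20, adjusted p = 0.0131), while TH1 (0.34 ± 0.077), TPK2 (0.62 ± 0.16) and TENA_E (0.47 ± 0.14) rose (adjusted over the list alone, 3 rose and 2 fell). Its median was 0.082 and its mean -0.072, and the test pointed upward. Thiamine genes as a set had a camera adjusted p of 0.718, and an adjusted p of 0.848 with an estimated correlation. The title names these genes here too, so the list is not independent evidence. The call of TPK2 ended without control replicate 3 (adjusted p = 0.0537), low-potassium replicate 2 (0.0551) or low-potassium replicate 3 (0.0547). TPK2 had adjusted p from 0.00516 to 0.0551 over 19 alternatives. That of TENA_E ended without control replicate 2 (adjusted p = 0.0736), control replicate 3 (0.0765), low-potassium replicate 2 (0.0913) or low-potassium replicate 3 (0.0638). TENA_E had adjusted p from 0.0122 to 0.0913 over 19 alternatives. In the authors' deposited table THIC changed by -1.0 and THI1 by -1.32 in log2, each with a q of 0.000491, again the lowest among the named genes and shared by many.

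Of 10 ABA receptor genes, 6 fell and 1 rose in low potassium (adjusted over the list alone, 1 rose and 7 fell). ABA receptor genes as a set had a camera adjusted p of 0.00984, and an adjusted p of 0.482 with an estimated correlation. PYL2 fell from 19.1 ± 3.70 to 4.21 ± 0.10 FPKM (log2 change -1.93 ± 0.13, adjusted p = 1.31e-05) and PYR1 by a log2 change of -0.36 ± 0.080, while PYL3 (1.03 ± 0.24) rose. Of 11 phosphatases and kinases after the receptors, 6 rose (7 adjusted over the list alone), all of them phosphatases: PP2CA (0.56 ± 0.085), HAB1 (0.54 ± 0.10), ABI1 (0.41 ± 0.092), HAI3 (1.27 ± 0.29), HAI2 (1.26 ± 0.32) and HAI1 (0.87 ± 0.28). Phosphatase and kinase genes as a set had a camera adjusted p of 0.00284, and an adjusted p of 0.482 with an estimated correlation. Of 18 ABA-responsive genes, 8 rose and ABF2 (-0.53 ± 0.11) fell (adjusted over the list alone, 8 rose and 1 fell). ABA-responsive genes as a set had a camera adjusted p of 0.0991, and an adjusted p of 0.774 with an estimated correlation. The ABA-responsive list passed without control replicate 2 (adjusted p = 0.0362) and low-potassium replicate 1 (0.0212). ABA-responsive genes as a set had camera adjusted p from 0.0212 to 0.414 over 17 alternatives. Of 9 genes of ABA synthesis and breakdown, 4 rose and CYP707A3 (-0.48 ± 0.10) fell (adjusted over the list alone, 4 rose and 1 fell). ABA synthesis and breakdown genes as a set had a camera adjusted p of 0.0628, and an adjusted p of 0.482 with an estimated correlation. NCED3, the enzyme that sets the rate of ABA synthesis, rose from 3.82 ± 0.656 to 15.4 ± 4.57 FPKM (log2 change 1.73 ± 0.20, adjusted p = 0.000264), together with CYP707A1 (1.04 ± 0.16), CYP707A4 (1.11 ± 0.24) and BG1 (0.99 ± 0.29). The set passed with a pseudocount of 0.1 (adjusted p = 0.0420), with a pseudocount of 0.5 (0.0486), without control replicate 2 (0.0377) and cesium replicate 2 (0.0476). ABA synthesis and breakdown genes as a set had camera adjusted p from 0.0377 to 0.25 over 17 alternatives. HAI2 lost its call without low-potassium 2 or low-potassium 3 (adjusted p from 0.00235 to 0.0537 with single libraries left out), HAI1 without control 1, control 3, low-potassium 2 or low-potassium 3 (0.00916 to 0.118) and BG1 without control 1, control 2, low-potassium 1 or low-potassium 2 (0.00551 to 0.0828).

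Of 22 glucosinolate genes, 17 fell and CYP79B3 (0.34 ± 0.12) rose (adjusted over the list alone, 1 rose and 17 fell), with a median of -1.13. Glucosinolate genes as a set had a camera adjusted p of 2.28e-07, and an adjusted p of 0.506 with an estimated correlation. CYP83A1, of the aliphatic branch, fell from 124 ± 9.02 to 18.3 ± 6.62 FPKM (log2 change -2.75 ± 0.23, adjusted p = 4.09e-05), and the transporter gene BAT5 by a log2 change of -1.15 ± 0.091. Of 10 genes of defense and phytoalexin synthesis, 5 rose and 2 fell (adjusted over the list alone, 5 rose and 2 fell), with CYP71A12 rising from 4.02 ± 1.19 to 55.6 ± 8.38 FPKM (log2 change 3.51 ± 0.33, adjusted p = 7.96e-05). Defense genes as a set had a camera adjusted p of 0.0152, and an adjusted p of 0.482 with an estimated correlation. The other members that rose were CYP82C2 (2.1 ± 0.19), CYP81F2 (1.93 ± 0.19), WRKY33 (0.88 ± 0.10) and MYB51 (1.03 ± 0.11), and WRKY53 (-1.0 ± 0.18) and WRKY40 (-0.69 ± 0.22) fell. Of 15 heat shock genes, 9 rose and HSFA2 (-0.49 ± 0.17) fell (adjusted over the list alone, 9 rose and 1 fell), with HSP18.2 rising from 10.1 ± 0.0621 to 75.2 ± 23.1 FPKM (log2 change 2.73 ± 0.25, adjusted p = 6.80e-05). Heat shock genes as a set had a camera adjusted p of 0.00633, and an adjusted p of 0.631 with an estimated correlation. Of 29 photosynthesis genes, 15 fell (16 adjusted over the list alone), and LHCB1.3 fell from 156 ± 18.1 to 79.2 ± 7.45 FPKM (log2 change -0.97 ± 0.18, adjusted p = 0.00295), while chloroplast-encoded genes took 0.140 to 0.193% of summed FPKM against 0.0802 to 0.125% in control. Photosynthesis genes as a set had a camera adjusted p of 2.29e-05, and an adjusted p of 0.631 with an estimated correlation. Of 20 jasmonate genes, 5 rose and 4 fell (adjusted over the list alone, 6 rose and 5 fell). Those that fell were JAZ3 (-0.78 ± 0.076), JAZ4 (-1.09 ± 0.16), JAZ9 (-0.72 ± 0.13) and AOC3 (-0.37 ± 0.11), and those that rose JAZ7 (0.92 ± 0.14), JAZ6 (0.36 ± 0.092), JAZ5 (0.52 ± 0.15), MYC2 (0.44 ± 0.13) and AOC2 (0.51 ± 0.17). The jasmonate median was 0.12 and the mean -0.040, with the test pointing upward. Jasmonate genes as a set had a camera adjusted p of 0.935, and an adjusted p of 0.971 with an estimated correlation. CYP79B3 lost its call without each of 6 libraries in turn (adjusted p from 0.00722 to 0.136 with single libraries left out), WRKY40 without each of 5 libraries in turn (0.0146 to 0.120), HSFA2 without each of 6 libraries in turn (0.0218 to 0.137), AOC3 without each of 5 libraries in turn (0.0152 to 0.0834), JAZ6 without control 2 (0.0113 to 0.0558), JAZ5 without control 2, control 3 or low-potassium 2 (0.0112 to 0.0747), MYC2 without control 2, control 3 or low-potassium 2 (0.00422 to 0.0904) and AOC2 without each of 5 libraries in turn (0.0192 to 0.134).

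Of 24 nitrogen genes, 9 fell and 8 rose (adjusted over the list alone, 8 rose and 9 fell). The list had a camera adjusted p of 0.253, and 0.848 with an estimated correlation. Nitrate transporter genes were among those that fell, NRT2.2 from 54.5 ± 20 to 0.905 ± 0.436 FPKM (log2 change -4.83 ± 0.34, adjusted p = 1.59e-05) and NRT2.6 by a log2 change of -3.08 ± 0.19. Of 13 phosphate starvation genes, 7 fell (7 adjusted over the list alone). The list had a camera adjusted p of 0.000262, and 0.482 with an estimated correlation. SPX1 fell from 36.3 ± 5.54 to 6.56 ± 0.488 FPKM (log2 change -2.30 ± 0.11, adjusted p = 2.60e-06), and IPS1 stood at 0, 0 and 0.118 FPKM in low potassium, listed at 0 in 2 libraries, against 7.91, 9.41 and 9.13 in control. Of 13 sulfur deficiency genes, 7 fell and 1 rose (adjusted over the list alone, 1 rose and 7 fell), the last being SULTR1.2, a sulfate uptake transporter (log2 change 1.94 ± 0.22, adjusted p = 0.000235). Sulfur genes as a set had a camera adjusted p of 0.208, and an adjusted p of 0.831 with an estimated correlation. FER3 (-0.54 ± 0.10), FER1 (-0.40 ± 0.12) and FER4 (-0.38 ± 0.12), 3 of the 4 ferritin genes, which store iron, fell (3 adjusted over the list alone). Ferritin genes as a set had a camera adjusted p of 0.0468, and an adjusted p of 0.482 with an estimated correlation. The ferritin set did not pass without control replicate 1 (adjusted p = 0.0731) or low-potassium replicate 1 (0.0513). Ferritin genes as a set had camera adjusted p from 0.0335 to 0.0731 over 17 alternatives. FER1 lost its call without control replicate 1 (adjusted p = 0.0847), control replicate 2 (0.0873), low-potassium replicate 1 (0.0716) or low-potassium replicate 3 (0.10). FER1 had adjusted p from 0.0173 to 0.10 over 19 alternatives. Of 24 iron deficiency genes, 8 fell and 5 rose (adjusted over the list alone, 6 rose and 8 fell), with the regulator FIT falling from 30.3 ± 3.40 to 13.5 ± 0.468 FPKM (log2 change -1.10 ± 0.093, adjusted p = 4.11e-05) and NRAMP1 (1.85 ± 0.10), AHA2 (1.16 ± 0.15), FRO3 (0.68 ± 0.12), OPT3 (0.73 ± 0.13) and BHLH101 (0.41 ± 0.13) rising. Iron genes as a set had a camera adjusted p of 0.718, and an adjusted p of 0.942 with an estimated correlation. Of 17 aquaporins, 9 fell and 3 rose (adjusted over the list alone, 3 rose and 10 fell), with TIP2.1 falling by a log2 change of -1.40 ± 0.15 and TIP2.2 (0.67 ± 0.13), TIP2.3 (0.88 ± 0.19) and PIP1.1 (0.63 ± 0.14) rising. Aquaporin genes as a set had a camera adjusted p of 0.0403, and an adjusted p of 0.661 with an estimated correlation. The aquaporin set did not pass without control replicate 1 (adjusted p = 0.0595) or low-potassium replicate 3 (0.0777). Aquaporin genes as a set had camera adjusted p from 0.0212 to 0.0777 over 17 alternatives. FER4 lost its call without each of 6 libraries in turn (adjusted p from 0.00334 to 0.101 with single libraries left out) and BHLH101 without each of 6 libraries in turn (0.0196 to 0.104).

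Of 20 root hair genes, 15 fell in low potassium (16 adjusted over the list alone), with RHD6, a regulator of root hair start, falling from 18.9 ± 0.429 to 10.4 ± 0.954 FPKM (log2 change -0.81 ± 0.12, adjusted p = 0.00107). The list had a camera adjusted p of 3.42e-05, and 0.631 with an estimated correlation. Of 9 Casparian strip genes, 6 fell (6 adjusted over the list alone), with CASP4 falling from 37.7 ± 4.24 to 13.1 ± 1.35 FPKM (log2 change -1.45 ± 0.13, adjusted p = 6.22e-05). The list had a camera adjusted p of 0.000645, and 0.494 with an estimated correlation. Of 11 suberin genes, 6 fell and 2 rose (adjusted over the list alone, 2 rose and 7 fell), the risen ones being FAR1 (1.36 ± 0.20) and FAR4 (0.34 ± 0.11). The list had a camera adjusted p of 0.0476, and 0.683 with an estimated correlation. The suberin call ended under median-ratio rescaling (adjusted p = 0.0501), without control replicate 3 (0.163), cesium replicate 1 (0.0656) or cesium replicate 3 (0.0760). Suberin genes as a set had camera adjusted p from 0.0182 to 0.163 over 17 alternatives. Of 18 dividing cell genes, 12 fell (13 adjusted over the list alone), with log2 changes of -0.71 to -0.30, among them KNOLLE, needed for the new wall of dividing cells, falling from 24.4 ± 3.36 to 14.5 ± 0.730 FPKM (log2 change -0.71 ± 0.11, adjusted p = 0.000991). The list had a camera adjusted p of 0.000262, and 0.566 with an estimated correlation. The 13 xylem wall genes had a median of -0.38. The list had a camera adjusted p of 0.253, and 0.848 with an estimated correlation. FAR4 lost its call without each of 5 libraries in turn (adjusted p from 0.0176 to 0.129 with single libraries left out).

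The genes that rose most by the rule also included AT1G14642, at 21.2, 10.7 and 41.8 FPKM in low potassium and listed at 0 in each control and cesium library, and the glycine-rich protein gene AT2G05510, which rose from 182 ± 13.6 to 4052 ± 1096 FPKM (log2 change 4.44 ± 0.31, adjusted p = 1.75e-05). Among those that fell most, AT4G33720, of a family of secreted cysteine-rich proteins, stood at 0.128, 0 and 0.0619 FPKM in low potassium, listed at 0 in low-potassium replicate 2, against 15.6, 18.7 and 16.9 in control. The low-potassium and control libraries did not overlap for 55.9% of tested genes, where chance gives 10.0%. Leaving out single libraries gave 5323 to 8643 changed genes.

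Cesium was then set against low potassium directly, which tests whether both treatments act alike on a gene and in which the control cancels. THIC was higher in cesium, at 12.9 ± 3.15 FPKM against 3.13 ± 0.120 in low potassium (log2 change 1.72 ± 0.20, adjusted p = 0.000246), and so was THI1, at 71.5 ± 21.2 against 18.7 ± 3.42 (log2 change 1.85 ± 0.23, adjusted p = 0.000391). HAK5 was lower in cesium (log2 change -5.19 ± 0.19, adjusted p = 1.00e-06), as were AKT1 (log2 change -0.86 ± 0.11, adjusted p = 0.000540) and RAB18 (log2 change -3.26 ± 0.23, adjusted p = 2.01e-05). AIR1 was higher (log2 change 5.69 ± 0.21, adjusted p = 1.00e-06). Of the tested genes 6677 passed with limma, 3268 higher and 3409 lower in cesium, 1024 of them by at least 1 on the log2 scale.

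Of the 7 thiamine genes, THIC and THI1 was higher in cesium (adjusted over the list alone, 2 were higher and 1 lower), and as the title names the list, this is not independent evidence. The list median was -0.069 and its mean 0.40, with the test pointing upward. Thiamine genes as a set had a camera adjusted p of 0.635, and an adjusted p of 0.850 with an estimated correlation. Of 10 ABA receptor genes, 6 were higher and PYL3 (-2.31 ± 0.24) lower in cesium (adjusted over the list alone, 6 were higher and 1 lower), with PYL6 (2.1 ± 0.13) and PYL2 (1.52 ± 0.13) differing most upward. The receptor list did not pass, but passed with a pseudocount of 0.1 (adjusted p = 0.0470), with a filter of 5 FPKM (0.00416), under quantile normalization (0.0360), without low-potassium replicate 2 (0.0430) or cesium replicate 3 (0.0241). ABA receptor genes as a set had a camera adjusted p of 0.0541, and an adjusted p of 0.435 with an estimated correlation. ABA receptor genes as a set had camera adjusted p from 0.00416 to 0.0872 over 17 alternatives. Of the 11 phosphatases and kinases, 9 were lower (11 adjusted over the list alone), with PP2CA at 25.5 ± 1.36 against 42.3 ± 1.23 FPKM (log2 change -0.71 ± 0.085, adjusted p = 0.000295) and HAI3 at 0.361 ± 0.101 against 6.18 ± 2.7 (log2 change -2.32 ± 0.29, adjusted p = 0.000375). Phosphatase and kinase genes as a set had a camera adjusted p of 9.11e-06, and an adjusted p of 0.435 with an estimated correlation. Of 18 ABA-responsive genes, 14 were lower (adjusted over the list alone, 1 was higher and 15 lower), with a median of -1.31, and KIN1 measured 136 ± 33.3 FPKM in cesium against 582 ± 201 (log2 change -2.07 ± 0.24, adjusted p = 0.000242). ABA-responsive genes as a set had a camera adjusted p of 8.10e-07, and an adjusted p of 0.435 with an estimated correlation. Of 9 genes of ABA synthesis and breakdown, NCED3 (-1.81 ± 0.20), CYP707A1 (-0.75 ± 0.16) and ABA1 (-0.57 ± 0.15) were lower and CYP707A4 (2.06 ± 0.24) and BG1 (1.15 ± 0.29) higher (adjusted over the list alone, 2 were higher and 3 lower), with a median of -0.17. ABA synthesis and breakdown genes as a set had a camera adjusted p of 0.537, and an adjusted p of 0.792 with an estimated correlation. ABA1 lost its call without low-potassium 2 (adjusted p from 0.0142 to 0.0599 with single libraries left out) and BG1 without low-potassium 3 (0.00266 to 0.0506).

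Of 34 genes listed under potassium transport, 16 were lower and 3 higher in cesium (adjusted over the list alone, 4 higher and 17 lower). The cation exchanger CHX17 measured 10.2 ± 4.36 against 125 ± 9.60 FPKM (log2 change -3.58 ± 0.25, adjusted p = 1.87e-05). Higher were the ABC transporter ABCG33 (1.03 ± 0.13), KUP2 (0.41 ± 0.078) and KEA1 (0.44 ± 0.11). The set had a camera adjusted p of 0.000621, and 0.464 with an estimated correlation. All 29 tested photosynthesis genes were higher (29 adjusted over the list alone), with a median of 1.70, among them LHCB1.3 (2.81 ± 0.18) and PSAG (2.08 ± 0.13). Photosynthesis genes as a set had a camera adjusted p of 6.07e-17, and an adjusted p of 0.435 with an estimated correlation. Chloroplast-encoded genes took 0.184 to 0.468% of summed FPKM in cesium and 0.140 to 0.193% in low potassium. Of 20 jasmonate genes, 14 were higher and AOC2 (-0.70 ± 0.17) and JAZ11 (-0.23 ± 0.067) lower (adjusted over the list alone, 15 were higher and 2 lower), with JAZ3 at 61.9 ± 3.29 against 25.1 ± 1.75 FPKM (log2 change 1.27 ± 0.076, adjusted p = 7.77e-06). Jasmonate genes as a set had a camera adjusted p of 1.82e-06, and an adjusted p of 0.435 with an estimated correlation. Of 22 glucosinolate genes, 16 were higher and CYP79B3 (-0.59 ± 0.12) lower (adjusted over the list alone, 17 were higher and 1 lower), with MYB28 at 72.3 ± 5.09 against 20 ± 3.48 FPKM (log2 change 1.82 ± 0.12, adjusted p = 1.39e-05). Glucosinolate genes as a set had a camera adjusted p of 8.09e-07, and an adjusted p of 0.464 with an estimated correlation. In cesium against control the glucosinolate list had a median of -0.15. Glucosinolate genes as a set had a camera adjusted p of 0.516, and an adjusted p of 0.844 with an estimated correlation. Of 18 dividing cell genes, 14 were higher (14 adjusted over the list alone), with differences of 0.42 to 0.74. Dividing cell genes as a set had a camera adjusted p of 4.15e-06, and an adjusted p of 0.435 with an estimated correlation. JAZ11 lost its call without low-potassium 1, low-potassium 2 or cesium 2 (adjusted p from 0.0313 to 0.0763 with single libraries left out).

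All 11 suberin genes were lower in cesium than in low potassium (11 adjusted over the list alone), with FAR4, which makes fatty alcohols of suberin, at 18.5 ± 2.1 against 42.9 ± 3.02 FPKM (log2 change -1.18 ± 0.11, adjusted p = 8.95e-05). Suberin genes as a set had a camera adjusted p of 8.10e-07, and an adjusted p of 0.435 with an estimated correlation. The root hair list had a median difference of -0.13 but passed without low-potassium replicate 3 (adjusted p = 0.00157), there with a median of -0.48. Root hair genes as a set had a camera adjusted p of 0.635, and an adjusted p of 0.926 with an estimated correlation. Root hair genes as a set had camera adjusted p from 0.00157 to 0.797 over 17 alternatives. Among 9 Casparian strip genes, CASP5 (-1.55 ± 0.21) and PER64 (-0.58 ± 0.11) were lower (2 adjusted over the list alone), and the set passed without cesium replicate 3 (adjusted p = 0.0414). Casparian strip genes as a set had a camera adjusted p of 0.240, and an adjusted p of 0.792 with an estimated correlation. Casparian strip genes as a set had camera adjusted p from 0.0414 to 0.484 over 17 alternatives. Of 13 phosphate starvation genes, 6 were lower (8 adjusted over the list alone), with PAP17 (-1.10 ± 0.16) and SQD2 (-0.88 ± 0.17). Phosphate genes as a set had a camera adjusted p of 0.0343, and an adjusted p of 0.435 with an estimated correlation. The phosphate set did not pass without low-potassium replicate 1 (adjusted p = 0.0555) or cesium replicate 1 (0.0732). Phosphate genes as a set had camera adjusted p from 0.0132 to 0.0732 over 17 alternatives. Of 24 nitrogen genes, 10 were lower and 6 higher (adjusted over the list alone, 6 were higher and 10 lower), with a median of -0.16, a mean of 0.18 and a test pointing downward. Nitrogen genes as a set had a camera adjusted p of 0.635, and an adjusted p of 0.926 with an estimated correlation. The libraries of both treatments did not overlap for 47.2% of tested genes, where chance gives 10.0%.

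Both stresses were also compared through the genes that each called against control. In the same direction 2337 genes were called in both, 962 higher and 1375 lower, and 336 in opposite directions. Of the latter, 177, such as THIC and LHCB1.3, were higher in cesium and lower in low potassium, and 159, such as RAB18 and GORK, a channel that lets potassium out, the reverse. The authors' deposited table called RAB18 in neither stress (q of 0.265 in cesium and 0.0679 in low potassium). Independent lists of these sizes would share 397 higher and 465 lower genes, and 398 and 465 in opposite directions. In 50 simulations, with all groups unchanged and controls shared, the mean overlap was 0 genes with limma. No gene changed there, so almost none passes the adjustment, and the 0 sets no baseline for the 2337. At an unadjusted p under 0.05 the simulated overlap was 215, where the data gave 3676. The log2 changes correlated at r = 0.46 across genes, which are not independent replicates, against 0.50 in the simulations. Their covariance was 0.123 against 0.015, a difference of 0.108. With 3 controls no split into groups of at least 2 was possible, so part of the excess may come from the shared controls. Without control replicate 2 the count in the same direction was 1498, and without control replicate 3 it was 1548.

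**Figure D2:**
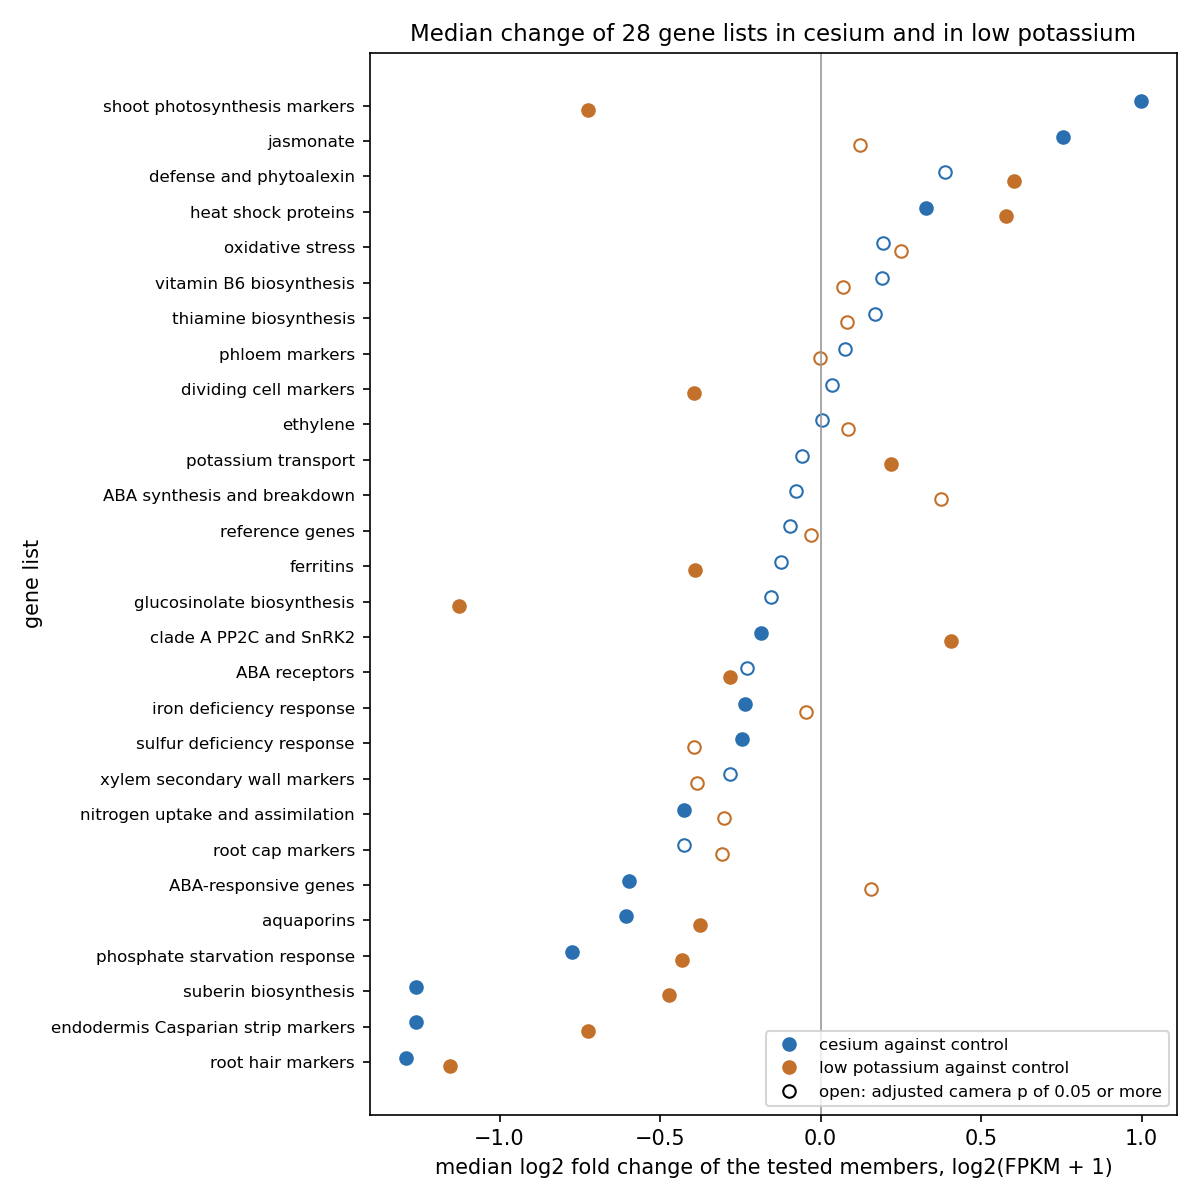
Median log2 change of the 28 gene lists in cesium and in low potassium against control, where filled points have an adjusted camera p under 0.05 at the preset correlation and open points do not. The photosynthesis list lies at 1.0 in cesium and -0.72 in low potassium, and the root hair list at -1.29 and -1.15.

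The authors' deposited table called 4713 genes for cesium and 6272 for low potassium. Of those tested here, 79.6% and 89.3% were also called here, each in the same direction. At the preset correlation 13, 14 and 9 of the 28 lists passed in cesium, in low potassium and between them. With an estimated correlation the lowest adjusted p was 0.102, 0.482 and 0.435, so that none of these calls held. By fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 9, 13 and 14 lists passed.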

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

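The tests of library scaling, of cesium library 3, of xylem and dividing tissue, of lists matched on expression and of time of day in cesium against control were chosen only after the result was seen. So were the conditions that the range without single libraries must stay on 1 side of a bound and that clock genes of a phase, and dividing cell genes, must not go both ways. The test of other splits was not. Those of shoot tissue and of time of day between both treatments used genes listed after the files were seen. They were therefore not fixed before the data.

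Photosynthesis genes were higher in cesium than in low potassium, with a median difference of 1.70, a call that did not hold with an estimated correlation (adjusted p = 0.435). A single scaling factor per library moves all genes the same way. Scaling as the whole cause is argued against, as the ABA-responsive list differed the other way, by -1.31. The median difference of all tested genes was -0.0024, between -0.0082 and 0.0018 without single libraries. It would also lie near 0 had the authors scaled the libraries to a common median, so it decides nothing here. Harvest at another time of day cannot be told apart from an effect of the treatments, since dawn and dusk clock genes moved apart by -0.98 (-1.06 to -0.94) between cesium and low potassium, beyond the 0.5 set against it, and the 0.14 (0.014 to 0.17) between cesium and control covers members that went both ways, such as CCA1 (-0.49, adjusted p = 0.0684), LHY (-0.42, adjusted p = 0.0551) and PRR7 (0.48, adjusted p = 0.0593) at dawn and ELF4 (-0.63, adjusted p = 0.103) and PRR5 (0.39, adjusted p = 0.0613) at dusk, none of which passed. Shoot tissue in the cesium roots cannot be told apart from a change in the roots: 12 shoot genes outside photosynthesis had a median log2 ratio of 0.13, but 1 of them reached 1 FPKM (ATML1), too few to decide, while TGG1 measured 0.0176 FPKM in control and 0.441 in cesium and YAB3 0.115 and 0.747. A response of the roots to either treatment stays open, untested.

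Root hair, Casparian strip and suberin genes were lower in cesium than in control, with list medians of -1.29, -1.26 and -1.26, calls that did not hold with an estimated correlation (adjusted p = 0.535, 0.345 and 0.345). Cesium library 3 as the cause is argued against, since 26 of the 40 members passed without it. A larger share of dividing tissue cannot be told apart from a change of these genes, since the dividing cell list, with a median of 0.036 (-0.046 to 0.13 without single libraries), went both ways, with WOX5 (0.76 ± 0.18) and PLT2 (0.58 ± 0.13) rising and AUR2 at -0.28 ± 0.10 without passing (adjusted p = 0.0796). A smaller share of mature root tissue as a whole stays open too, because the xylem list, with a median of -0.28, ranged from -0.60 to 0.013 without single libraries. A response of these genes to cesium stays open beside them, untested.

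ABA-responsive genes were lower in cesium than in low potassium, with a median difference of -1.31, a call that did not hold with an estimated correlation (adjusted p = 0.435). A shift shared by genes of similar expression is argued against, as the median lay at percentile 0 of 10000 lists matched on expression, whose central 95% ran from -0.17 to 0.27. Those lists draw genes at random, while the members moved together (estimated correlation 0.31), so the percentile does not test the list itself. Scaling is argued against by the median of all genes given above, -0.0024, and cesium library 3 by the 13 members that were lower without it. A difference in ABA response between the treatments stays open as a hypothesis, since ABA itself was not measured. Differences between the treatments in growth or in water status stay open, untested. Harvest at another time of day stays open here too, since dawn and dusk clock genes moved apart by -0.98 between cesium and low potassium.

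Other lists stood out because the direct test between cesium and low potassium passed. The median log2 difference was -0.70 for the phosphatase and kinase list, -0.31 for the potassium transport list, -0.34 for the phosphate list and -0.85 for the suberin list, and it was 0.73 for the jasmonate list, 1.16 for the glucosinolate list and 0.50 for the dividing cell list. These calls were made at the preset correlation, and none held with an estimated correlation, where the lowest adjusted p was 0.435.

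Single genes stood out because both stresses changed them in opposite directions against control and the direct test between cesium and low potassium passed. That test passed for all 336 genes called in opposite directions against the shared controls, so it is no separate support. Higher in cesium than in low potassium, with the log2 difference, were AIR1 (5.69), AT3G02620 (4.98), AT3G29252 (4.74), AT5G61290 (4.16), LHCB1.3 (2.81), PSAG (2.08), LHCB3 (1.74), THIC (1.72), JAZ9 (1.41), PSBX (1.37), JAZ3 (1.27), PIP2.8 (1.03) and CSD2 (0.74). Lower were CEP1 (-3.47), DIR1 (-3.36), RAB18 (-3.26), HAI3 (-2.32), PYL3 (-2.31), TIP2.2 (-1.60), NPF7.3 (-1.57), GORK (-1.26), BHLH101 (-1.19), FAR4 (-1.18) and ABI1 (-0.85). Against control, part of these calls ended without single libraries, with the range of the adjusted p in parentheses: in cesium HAI3 without each of 5 libraries in turn (0.00979 to 0.0995), PSBX without each of 4 libraries in turn (0.0134 to 0.123), PIP2.8 without control replicate 3 (0.0122 to 0.0548) and CSD2 without each of 3 libraries in turn (0.00877 to 0.0705), and in low potassium BHLH101 without each of 6 libraries in turn (0.0196 to 0.104) and FAR4 without each of 5 libraries in turn (0.0176 to 0.129). AT3G29252 was listed at 0 in low-potassium replicate 2, at 0.615, 0 and 0.149 FPKM in the low-potassium libraries, 1.06, 1.50 and 1.07 in control and 38.2, 28.3 and 30.0 in cesium. In the authors' deposited table RAB18 (q of 0.265 in cesium and 0.0679 in low potassium) and BHLH101 (0.146 and 0.299) passed in neither stress. DIR1 (0.252) and CSD2 (0.0610) did not pass there in cesium, nor AT3G29252 (0.139) and AT5G61290 (0.247) in low potassium.

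The 6 libraries of each comparison make 10 splits into 3 and 3, which are too few for a share under 0.05. Fitted on those 6 libraries, the real split called 3752 genes for cesium, 8320 for low potassium and 5578 between them, and the highest of the other splits called 2, 1 and 1. Each other split mixes libraries of both groups on each side, so the treatment difference adds to the spread and few calls follow. Those counts are therefore no measure of chance. The real split was the 1 split of 10 with as many genes in each comparison.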

How the results depend on the processing

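Leaving out genes listed at 0 in 1 library was chosen after the data were seen. No called result turned its direction under any alternative run. The counts of genes changed by cesium (4591) and of genes called in both stresses in the same direction (2337) ranged over 2905 to 4788 and 1498 to 2673 with single libraries left out, and those for low potassium and between the treatments over 5323 to 8643 and 4832 to 6602. Fewer libraries leave fewer degrees of freedom, and the cause of the low counts without control replicates 2 and 3 was otherwise not tested. With a log2 change of at least 1 also asked, the counts fell to 934 for cesium, 1196 for low potassium, 1024 between them and 363 in the same direction in both stresses, by the construction of that alternative. Under the other alternatives (pseudocounts, filters, scalings, the fit on 6 libraries, no trend, the authors' q-values) each count that was run stayed within 1.5 times its value, the authors giving no q-values for cesium against low potassium. The median log2 change of all genes stayed under 0.1 in size under each scaling, though median-ratio and quantile scaling bring it near 0 by construction.

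Of the 84 list results, 36 passed at the preset correlation and 32 to 37 with single libraries left out. With an estimated correlation 0 passed in camera, where an unadjusted p was under 0.05 for 4 lists in cesium, 1 in low potassium and 1 between them, and fry passed 9, 13 and 14. The estimated correlations differ from the preset, and no other cause was tested. Among lists that passed in neither fit, the sign of the test changed for up to 8 (without cesium replicate 3). Of the 243 values of named genes, 193 to 207 passed with single libraries left out, and up to 3 that did not pass changed sign in any 1 alternative. With a filter of 5 FPKM 23 of them were not tested.

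The values showed no consistent pairing of the libraries by replicate number, and the labels do not state one. Deviations of same-numbered libraries correlated between -0.12 and 0.28 across genes, above 0.1 in 3 of 9 pairs, and 1 library correlated best with its own number in both other groups. The 0.28 was that of low-potassium replicate 3 with cesium replicate 3, so an effect shared by both is not excluded. With the number as a block, 4154 genes were called for cesium, 6729 for low potassium, 6095 between them and 2151 in the same direction in both stresses. Among lists the suberin call in low potassium ended (adjusted p = 0.0591), and among values of named genes 2 calls ended, that of PDX2 in cesium (adjusted p = 0.0553) among them, and 5 were gained.

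A test on counts was not run, since the files hold FPKM. With the absolute depth unknown, what counting error limits at low FPKM is not known.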

Other observations

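Gene families were tested by the descriptions of the deposited table, a test chosen only after the data were seen. The clock genes were listed after the files were seen as well.

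Some fixed lists have not been described so far. Of 10 defense genes, CYP82C2 (0.72 ± 0.19), CYP71A12 (1.16 ± 0.33) and CYP81F2 (0.59 ± 0.19) rose in cesium and WRKY53 (-0.62 ± 0.18) fell (adjusted over the list alone, 4 rose and 1 fell). Defense genes as a set had a camera adjusted p of 0.109, and an adjusted p of 0.535 with an estimated correlation. CYP71A12 lost its call with no filter on low values (adjusted p = 0.0610), in a fit on 6 libraries (0.0722), without control replicate 1 (0.103), control replicate 3 (0.0781), low-potassium replicate 2 (0.0510), cesium replicate 1 (0.0925) or cesium replicate 2 (0.0960), and CYP82C2 without control replicate 1 (adjusted p = 0.0670), control replicate 3 (0.0767), cesium replicate 1 (0.0695) or cesium replicate 2 (0.0754). CYP71A12 had adjusted p from 0.000866 to 0.103 over 19 alternatives. CYP82C2 had adjusted p from 0.00619 to 0.0767 over 18 alternatives. Of 23 ethylene genes, ERF1A (0.66 ± 0.15), EBF1 (0.46 ± 0.11) and ERF2 (0.58 ± 0.18) were among 4 that rose in cesium, and ACS5 (-1.31 ± 0.17), ACO1 (-0.77 ± 0.11), ACS6 (-1.07 ± 0.16) and RAP2.11 (-1.41 ± 0.36) fell (adjusted over the list alone, 4 rose and 6 fell), with a median of 0.0039, a mean of -0.093 and a test pointing downward. Ethylene genes as a set had a camera adjusted p of 0.687, and an adjusted p of 0.814 with an estimated correlation. Of 9 genes often used as references, ACT2 (-0.36 ± 0.088) fell in cesium (1 adjusted over the list alone). Reference genes as a set had a camera adjusted p of 0.220, and an adjusted p of 0.673 with an estimated correlation. ACT2 lost its call without control replicate 2 (adjusted p = 0.0525) or control replicate 3 (0.0518). ACT2 had adjusted p from 0.00942 to 0.0525 over 19 alternatives. It fell in low potassium too, with adjusted p from 0.00805 to 0.0407 over 19 alternatives. CYP81F2 lost its call without each of 7 libraries in turn (adjusted p from 0.0248 to 0.160 with single libraries left out), WRKY53 without each of 5 libraries in turn (0.0164 to 0.114), EBF1 without control 2 (0.0113 to 0.0605), ERF2 without each of 7 libraries in turn (0.0119 to 0.138) and RAP2.11 without control 2, control 3 or cesium 3 (0.00119 to 0.0718).

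Of 115 families with at least 15 tested genes, 25 passed with camera in cesium, 14 in low potassium and 14 between them at the preset correlation. With an estimated correlation none of these calls held, the lowest adjusted p being 0.633, 0.614 and 0.576. Of 17 dirigent-like genes, whose products guide the coupling of lignin and lignan precursors, 11 fell and 1 rose in cesium, and 13 fell in low potassium. Dirigent-like genes in cesium had a median of -0.60 and a camera adjusted p of 7.76e-05, and an adjusted p of 0.633 with an estimated correlation. Dirigent-like genes in low potassium had a median of -0.71 and a camera adjusted p of 3.05e-05, and an adjusted p of 0.665 with an estimated correlation. Of 19 invertase/pectin methylesterase inhibitor superfamily genes, 10 fell in cesium. These 19 had a median of -0.56 and a camera adjusted p of 0.000195, and an adjusted p of 0.666 with an estimated correlation. Of 49 pectin lyase-like genes, 20 fell in low potassium. Pectin lyase-like genes in low potassium had a median of -0.24 and a camera adjusted p of 8.89e-05, and an adjusted p of 0.614 with an estimated correlation. Of 35 genes of the MATE family of efflux carriers, 17 rose and 2 fell in cesium. MATE genes in cesium had a median of 0.31 and a camera adjusted p of 0.00362, and an adjusted p of 0.666 with an estimated correlation. Of 41 thioredoxin family genes, 18 rose and 2 fell. Thioredoxin genes in cesium had a median of 0.30 and a camera adjusted p of 0.00162, and an adjusted p of 0.684 with an estimated correlation. Of 194 RING/U-box genes, 73 were lower and 10 higher in cesium than in low potassium, and 73 rose and 17 fell in low potassium against control. RING/U-box genes in cesium against low potassium had a median of -0.21 and a camera adjusted p of 0.000158, and an adjusted p of 0.576 with an estimated correlation. RING/U-box genes in low potassium had a median of 0.20 and a camera adjusted p of 0.000745, and an adjusted p of 0.614 with an estimated correlation.

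Clock genes moved in low potassium, where 10 of 12 passed with limma. The median log2 change was 0.74 over 6 genes that peak around dawn and -0.11 over 6 that peak around dusk. Among the former, RVE8 (0.91 ± 0.15, adjusted p = 0.00161), PRR9 (0.89 ± 0.17, adjusted p = 0.00334) and LHY (0.63 ± 0.14, adjusted p = 0.00735) rose, as did the remaining 3, and among the latter ELF4 (-1.04 ± 0.26, adjusted p = 0.0114), LUX (-0.34 ± 0.081, adjusted p = 0.0101) and FKF1 (-0.37 ± 0.12, adjusted p = 0.0327) fell, while TOC1 (0.29 ± 0.084, adjusted p = 0.0247) rose. Between cesium and low potassium 8 passed, with medians of -0.72 and 0.26. In cesium against control 0 of 12 passed with limma, and 5 had an unadjusted p under 0.05.

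MT1A took the largest share of FPKM in each of 8 libraries, at 8.14% of the sum in control replicate 1 up to 11.1% in low-potassium replicate 2, and was listed at 0 in cesium replicate 3, where the highest gene took 0.545%. Further genes listed at 0 in a single library with a mean of at least 5 FPKM in the others were U12 in control replicate 3, AT2G35850 in control replicate 2, and AT3G29252, AT3G41761 and AT4G33720 in low-potassium replicate 2, with means in the others of 9.04, 6.94, 12.6, 18 and 9.56 FPKM. Genes of the mitochondrial genome took 0.0517 to 0.0581% of summed FPKM in cesium, 0.0345 to 0.0420% in low potassium and 0.0129 to 0.0184% in control.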
